A study of Caulobacter vibrioides NA1000 with 2 samples.

How the data were processed

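Hi-C was performed by the authors with the restriction enzyme BglII on cells fixed with 1% formaldehyde, per the labels' protocols. The deposited values are a signal per pair of bins. Each of the 2 libraries has 1 symmetric square map of 405 bins without a header, spanning 4050 kb at an assumed 10 kb per bin. Rows sum to between 0.998 and 1.0019, and values are rounded to 4 decimals. The diagonal and neighbouring bins are listed at 0 except for the pair of the first and last bin. Row sums near 1 are those of a balanced map, so a value is read here as a share and not a count. Bowtie2 (version 2) is named in the submitters' processing notes. The genome build, bin size, filters, balancing method and sequencing depth are not given in the sources used here. Balancing removes differences in total coverage between bins, so a loss of DNA at the cut cannot be read from the maps, and rounding leaves few steps for weak contacts.

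Groups came from the labels, with 1 library for the induced break and 1 without it. With 1 library per group no test between groups was possible and none was made. The bin size was taken as 10 kb and the first bin as oriC, and this was checked on the data. With the gene table of the NA1000 assembly ASM2200v1 (4097 genes, 671 with a symbol), the last gene falls into the last bin at 10 kb, and the 6 bins with ribosomal protein or rRNA genes had a median insulation of -0.75 in the break library and -0.89 in the control, lower than under any other circular shift in both. The gene coordinates of the table placed genes into bins, and the end of the last gene set the possible break site left of oriC. In 14 bins (3.46%) the profile matched that of the bin before within 2% in both maps.

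Pairs at least 20 kb apart were used, and each map was scaled to the same total. Log2 ratios are break over control and leave out pairs listed at 0 in either map. Expected contact was the mean at each distance over the circle. Local and far contacts were medians over a window of 50 kb to each side, split at 200 kb. Insulation used 100 kb on each side and was averaged over both edges of a bin. Boundaries were minima within 30 kb with a depth of at least 0.1 (log2) below their flanks. The arms were divided into 3 equal parts and mirrored pairs taken within 50 kb of the axis. Gene lists were compared with 10000 random lists of as many bins matched on quintiles of control insulation. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

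Groups, the main measures, gene lists, 17 of the 21 alternatives and the rule for named genes were fixed before the data were examined, and 4 alternatives were added afterwards. Some measures were not in that plan. These are contacts of the oriC window by partner distance, contacts of the parAB bin, contacts between flanks alone, and contacts between parts of the arms. The rule names the bins of oriC, of both possible break sites, of the point opposite oriC and of the van locus, the 10 bins with the highest profile change, and the 5 bins with the largest rise and the 5 with the largest fall of insulation, with at most 3 named genes per bin. Genes are vanA, vanB, recA, lexA, dnaA, parA and parB, and from each list up to 4 members in the 10% of bins with the largest insulation change (0.22 or more). This named 23 genes. The gene table has no products, so a symbol other than a locus tag stood in for a known product, and a list of mobile elements was not analysed here. Other genes beside boundaries were named after their values were seen.

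Insulation was tested on simulated data made from the control map with pixel noise. All 20 positions given 0.5 (log2) fewer contacts across them were among the lowest values, with a mean recovered change of -0.46. The simulation covers pixel noise and rounding, not differences between cultures or library preparations. Alternatives were further balancing, values as deposited, leaving out bins with the lowest 5% of totals, a median expectation, a pseudocount, other windows, distances and boundary rules. Without replicates, an alternative value was called moved when it differed by more than the SD over positions, over 9 segments, over stretches of the arms or over random lists, and for counts by more than 1.5 times. Positions of 1 map are correlated, so these spreads describe the map and not experimental error.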

Results

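The folding of the chromosome was measured by Hi-C, in which crosslinked DNA is cut, ligated and sequenced so that pairs of loci lying close together in the cell are counted. The cells were swarmer cells of Caulobacter crescentus (strain NA1000), a bacterium with 1 circular chromosome. DnaA, the protein that starts replication, was depleted for 1.5 h before synchronisation, and the labels give the cells as G1-arrested. The strain carries a site for the endonuclease I-SceI 33 kb from the replication origin oriC and the I-SceI gene at the van locus, whose promoter responds to vanillate. In the break library, 500 µM vanillate was added for 1 h to induce I-SceI. In the control library no vanillate was added. Each group has 1 library, so no difference below has a replicate check and no p-value is given. Each value is instead set against the same value at all other positions of the map, which describe these libraries and are not replicates. Vanillate and the break came together, so the libraries differ in both. How far the site was cut was not measured in the files used here.

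Each deposited map is a square of balanced contact values, which sum to about 1 per row, so a value is the share of a bin's contacts that falls to its partner. Contact values are given below per 10000 contacts of a bin. The sequencing depth is unknown, because the values carry no counts. The median value was 12 in the break library and 10 in the control library over 81405 pairs. The share of pairs listed at 0 was 0.351% in the break library and 5.03% in the control. Neighbouring pairs between 400 and 800 kb apart scattered by 13.1% in the break map and 11.7% in the control map. Since every row has the same total, more contact at some distances comes with less at others. Positions assume 10-kb bins counted from oriC, and are therefore given in kb of the map rather than as genome coordinates.

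The contact maps shared their main features. With distance taken out, the contact values of the libraries correlated at a Spearman coefficient of 0.87 and a Pearson coefficient of 0.92 over 77132 pairs, which are not independent replicates. In 9 segments of the chromosome the Spearman coefficient ranged from 0.61 to 0.94. The main diagonal and a second stripe of contacts between the chromosome arms were visible in both maps. The break map had weaker contrast, and regions nearly empty in the control held more contact. The median log2 ratio of break to control was 0.14 over the 77132 pairs above 0 in both maps. It leaves out pairs at 0, most of them in the control. The median was 0.04 after a uniform floor was removed, taken as the 5% quantile of each map's values. This floor was 2.0 in the break map and 0.0 in the control, so only break values were reduced.

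**Figure D1:**
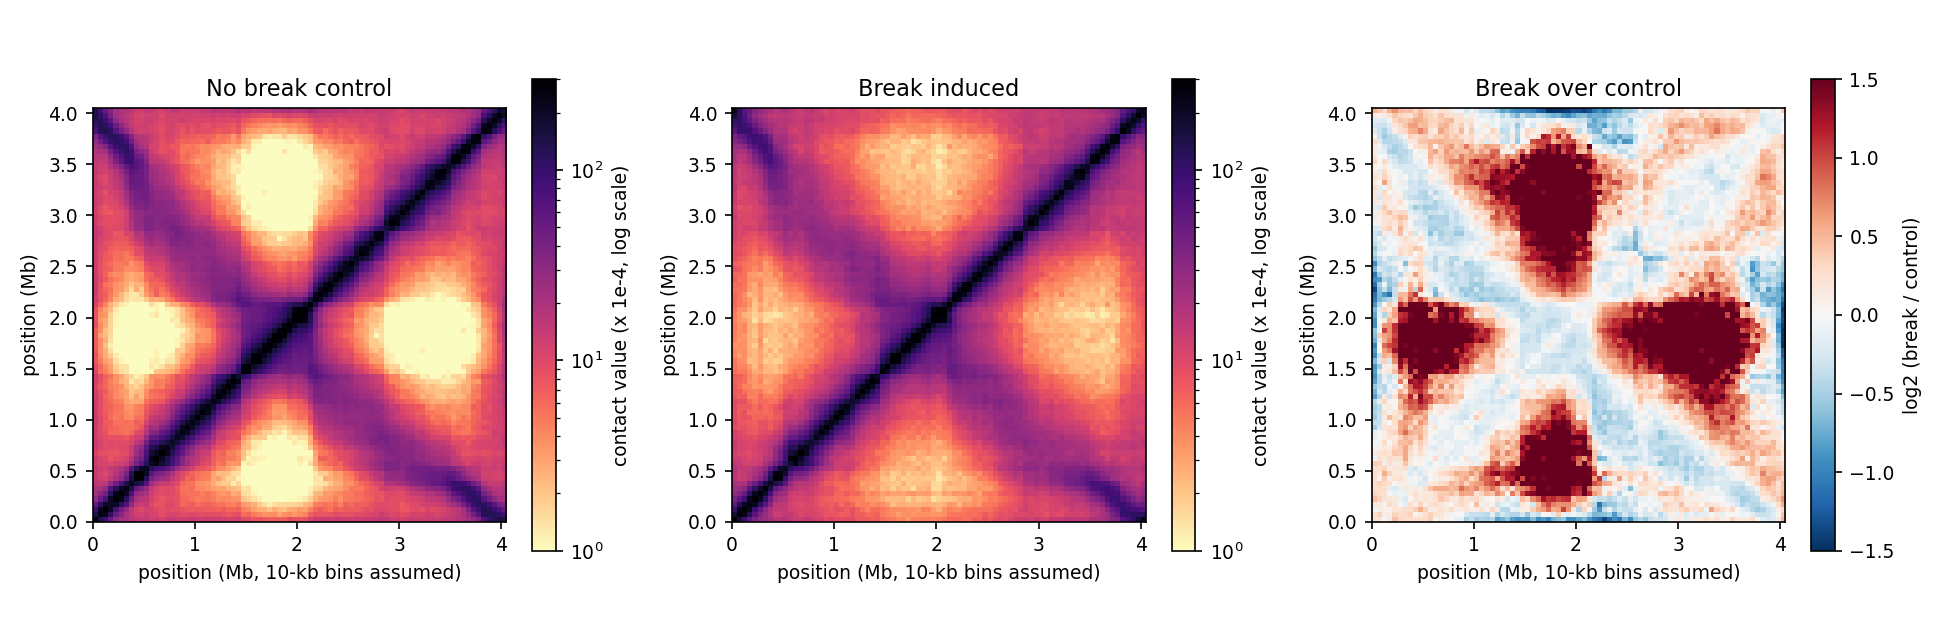
Mean contact values of the control library (left) and the break library (centre) in blocks of 5 bins, with chromosome position in Mb on both axes and a log colour scale, and their log2 ratio (right, colours end at -1.5 and 1.5). Red areas between the terminus and the arms mark more contact in the break library, and the blue edges at oriC mark less contact between oriC and the terminus region.

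Mean contact was higher in the break library at intermediate distances and at the shortest, and lower in between. At 20 to 30 kb it was 299.2 in the break library against 289.5 in the control, a log2 ratio of 0.05, with 63.5% of bins higher. Between 410 and 800 kb the mean contact value was 17.3 in the break library against 15.2 in the control, 14.2% higher, and 80% of the bins had more contact. Between 810 and 1200 kb it was 11.9% higher, with 69.4% of bins higher. Between 40 and 100 kb it was 154.2 against 165.9, a log2 ratio of -0.11, with 11.9% of bins higher. Between 110 and 200 kb the log2 ratio was -0.13. At 1210 to 1600 kb and at 1610 to 2020 kb it was 0.02 and -0.06. Contact declined with distance with a log-log slope of -0.98 in the break library and -1.08 in the control from 30 to 800 kb, a difference of 0.10. This is about the SD of the difference over 9 segments of the chromosome (0.102), and it was 0.048 with the uniform floor removed.

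By rank correlation, the contact profiles of the origin region differed most between the libraries. The 10 bins with the highest profile change, defined as 1 minus the Spearman correlation of a bin's distance-normalised contacts, all lay within 80 kb of oriC. They had values from 0.711 to 1.29 against a median of 0.138 over all bins. These bins have flat far contacts in the control, with coefficients of variation of 0.131 to 0.370 against a median of 0.910 over all bins, and a flat profile by itself lowers a rank correlation. In maps simulated from the control with pixel noise alone, their profile change reached at most 0.218. The bin with 1.29, at 4040 to 4050 kb, holds hemE and hemH, genes of haem synthesis, and is filled only in part by the chromosome. The bin at 4020 to 4030 kb (1.07) holds cenR and ldtX. The oriC bin itself (0.908) holds dnaA and the chaperone gene dnaK. The bin at 4030 to 4040 kb (0.804) holds gidA, rho and trmE together with parA and parB, whose products segregate the origin. The others were the bin with ftsK and ubiE (0.919), a bin without named genes (0.90), those with ubiB and fabI (0.870), moeB and dipI (0.849), and glnD, mutS and dnaJ (0.765), and the bin with the cell-shape gene creS and oxyR (0.711). This ranking came from far contacts: within 500 kb only 2 of the 10 highest bins lay within 100 kb of oriC.

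In the control library oriC contacted the terminus region more than in the break library. Over the 110-kb window around oriC, contact with bins 1610 to 2020 kb away averaged 6.31 in the break library and 13.4 in the control, a 2.12-fold difference with a log2 ratio of -1.09. At 1210 to 1600 kb the means were 8.90 and 13.4. At 410 to 800 kb the order was the opposite, 16.4 against 14.4. The difference was larger at the parAB bin, where contact with bins 1610 to 2020 kb away averaged 9.85 ± 2.06 in the break library and 27.9 ± 6.88 in the control (SD over 84 pairs of 1 library each), 2.83-fold. In the control, contact of the parAB bin rose from 13.98 at 810 to 1200 kb to 27.9 at 1610 to 2020 kb. In the break library it declined from 14.8 to 9.85 over the same distances. The median log2 ratio of all contacts of the oriC window beyond 200 kb was -0.26 (interquartile range -0.83 to 0.18 over 4001 pairs), the lowest value among all positions, whose median was 0.22, and shared by the windows of the next bins at 10 to 30 kb.

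**Figure D2:**
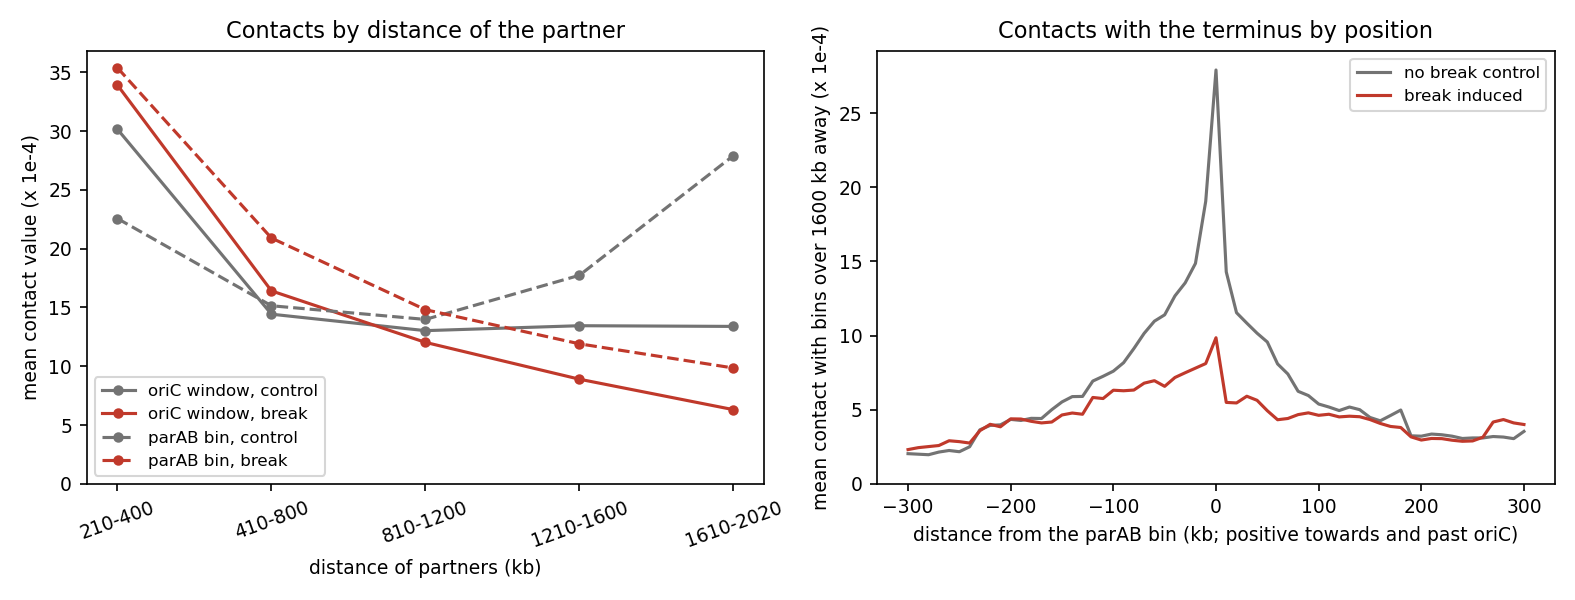
Left, mean contact value of the 110-kb oriC window (solid) and the parAB bin (dashed) by distance of the partner in kb, in the break library (red) and the control library (grey). Right, mean contact with bins over 1600 kb away for each bin within 300 kb of the parAB bin; in the control it reaches 27.9 at the parAB bin against 9.85 in the break library.

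At the break site, the question is whether the cut region gained or lost contacts. The labels place the site 33 kb from oriC without naming the side, so both positions were measured. Contacts of the 110-kb window on the right side (30 to 40 kb) with bins within 200 kb had a median log2 ratio of 0.17 (interquartile range -0.01 to 0.34 over 418 pairs), at percentile 99.1 of all positions. On the left side (4000 to 4010 kb) the ratio was 0.05 (-0.10 to 0.29), at percentile 89.5. The right side no longer lay outside the central 95% of positions with a window of 100 kb to each side (0.15) or a split at 400 kb (0.17), where the left side did (0.20). With partners beyond 200 kb the right side had a ratio of -0.24 (-0.74 to 0.17 over 4001 pairs), at percentile 0.988, and the left side -0.11 (-0.68 to 0.26), at percentile 3.09. The windows overlap that of oriC, where the ratios were 0.17 and -0.26, so the values do not separate the site from the origin. The point opposite oriC, at 2020 to 2030 kb, had a far ratio of 0.42, at percentile 86.2.

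Contacts across the site were not lower in the break library on either side by the insulation score over 100 kb. This score is the log2 mean contact between the 100 kb on either side, relative to distance, and lower values mean fewer contacts across. On the right side it was -0.36 in the control and 0.01 in the break library, a change of 0.37 at percentile 99.4. On the left side it was 0.26 and 0.37, a change of 0.11 at percentile 81.9. At oriC it was -0.00 and 0.36. The 5 largest increases were at the 5 bins from 0 to 50 kb, with changes from 0.36 to 0.38. They hold dnaA, dnaK and dnaQ, then glnD, mutS and dnaJ, then cckO, then pnp, vapC and vapB, and then nusA. With 200 kb on each side the changes at the right and left positions were 0.12 and -0.17, both inside the central 95% of positions, so the right side no longer stood apart and the left side had the opposite sign. With the site bin and 3 bins to each side left out, contacts between the flanks had a median log2 ratio of 0.28 on the right (percentile 97.3) and -0.15 on the left (percentile 44.8).

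The largest decrease of contacts across a position was at the van locus, far from the break site. The bin at 2620 to 2630 kb holds vanA and vanB, enzymes that break down vanillate, and vanR, their repressor. Its insulation score was 0.15 in the control library and -0.30 in the break library, a change of -0.45, the lowest of all bins (SD over bins 0.130). The 5 bins with the largest decreases were contiguous, from 2610 to 2660 kb, with changes of -0.35 to -0.45; besides the van genes they hold pssZ, sdpC, hfsE and hfsF. Contacts between the flanks were lower even without the bins at the locus. With the van bin and 3 bins to each side left out, contacts between the flanks within 100 kb had a median log2 ratio of -0.69 (interquartile range -0.78 to -0.47), 0.619-fold, and 48 of 49 pairs were lower in the break library. Contacts within each flank had a median log2 ratio of 0.13. In maps simulated with pixel noise alone, the insulation change had an SD of 0.025 and did not exceed 0.085 at any position.

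**Figure D3:**
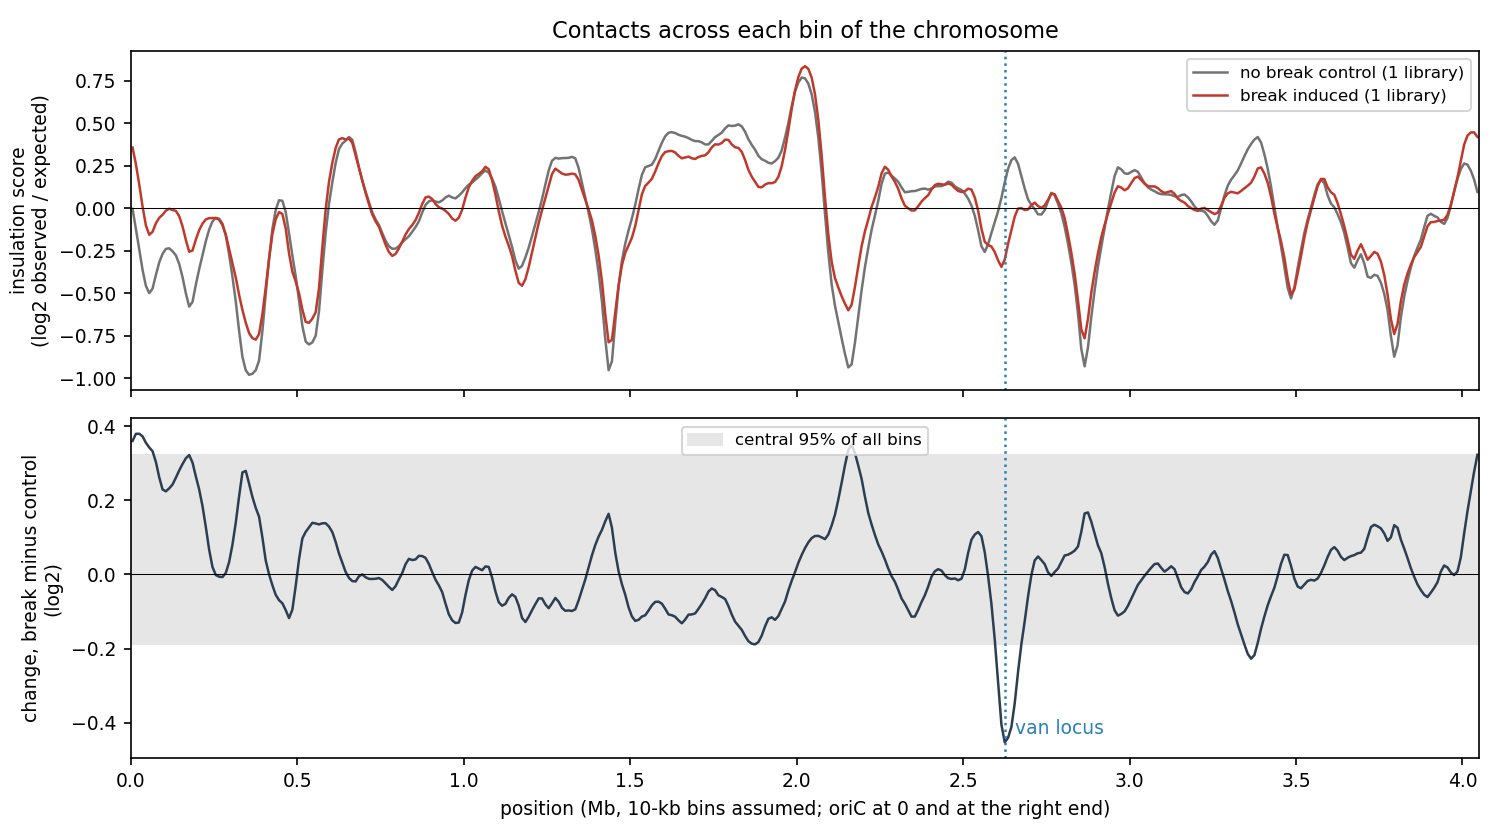
Top, insulation score (log2 observed over expected contact across each bin) along the chromosome in Mb, in the control library (grey) and the break library (red). Bottom, the change, break minus control, with the central 95% of all bins shaded; the lowest value, -0.45, is at the van locus (dotted line).

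Boundaries between domains lay at many of the same positions in the libraries. There were 17 local minima of insulation in the break library and 15 in the control, and 10 were shared within 1 bin. Circular shifts of 1 list gave 1.87 shared boundaries on average, and 0.495% of the shifts gave as many as 10. Among the shared boundaries were those beside the ribosomal protein cluster at 1440 kb (-1.01 in the control, -0.84 in the break library), the surface-layer genes around rsaA at 1170 kb (-0.36 and -0.47) and the nuo genes of respiratory complex I at 2160 kb (-0.97 and -0.62). Others lay beside lnt and mviN at 60 kb, hvyA and pulD at 180 kb, metE at 530 kb in the break library and 540 kb in the control, mutL and ileS at 790 kb, cspC at 2860 kb, nusG and dnaE2 at 3490 kb, and zapE at 3800 kb. In 8 of the 10 shared boundaries contact across was higher in the break library, with a median change of 0.15. The exceptions were those at 790 and 1170 kb. A line of break on control insulation had a slope of 0.79, and 7 of the 10 lay below it and 3 above, the latter at 60, 180 and 2160 kb. The boundary at 2620 kb beside vanR was found in the break library only, at -0.36 with a depth of 0.39. The control had 0.10 there and no minimum. With insulation over 50 kb the counts were 31, 28 and 24 shared.

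The arms of this chromosome lie side by side, which gives contacts between mirrored positions. With each arm divided into 3 equal parts, pairs mirrored about oriC had in the oriC-proximal part a median log2 ratio of 0.00 (interquartile range -0.17 to 0.19 over 671 pairs). The ratio was 0.28 (0.08 to 0.49 over 737 pairs) in the middle part and 0.74 (0.44 to 0.94 over 671 pairs) in the terminus-proximal part. There 93.7% of pairs were higher in the break library or listed equally in both maps. Observed over expected contact in the terminus-proximal part was 1.70 in the break library and 1.09 in the control. The direction turned on the strongest inter-arm contacts, which did not lie on the oriC mirror axis. They were displaced by 120 kb in the oriC-proximal part, 380 kb in the middle and 400 kb in the terminus-proximal part, an axis located after the maps were seen. On that axis the break library was lower in each part, with median log2 ratios of -0.30, -0.19 and -0.27. Of the 415 pairs of the terminus-proximal part, 90.8% were lower. The values at mirrored positions therefore describe contacts beside the inter-arm stripe. In the terminus-proximal part the displaced axis ends short of the point opposite oriC, so some of its 415 pairs lie on the same arm.

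Among the gene lists, no list stood outside the central 95% of random lists of as many bins with matched control insulation. The lists cover positions in the map, not expression, and expression was not measured here. Names without a match in the gene table left out 10 members of the DNA repair list (21 genes matched), 10 of replication and segregation (20 matched) and 6 of chaperones and stress (8 matched). DNA repair and SOS genes had a median insulation change of -0.01 (percentile 14.9 of 10000 random lists), with 7 of 15 bins higher. Within it, recA, the recombinase that acts on broken ends, lay in a bin with a change of -0.08, and lexA, the SOS repressor, in a bin with 0.20. The mismatch repair gene mutS (0.38), the division inhibitor gene sidA (0.34) and recF (0.31) were in bins with large changes. Of these, mutS lies next to oriC and sidA next to the nuo boundary. Replication and segregation genes had a median change of 0.03 (percentile 87.6), with 10 of 16 bins higher: dnaA 0.36, dnaE 0.34, gyrB 0.31, and parA, parB and gidA 0.28 in their shared bin. Cell cycle regulators had 0.01 (percentile 59.4), with the protease genes clpP, clpX and lon in 1 bin at 0.29. Ribosomal protein genes had 0.15 (percentile 88.5), with 4 of 4 bins higher, and rRNA genes 0.15 (percentile 50.3), with 2 of 2 bins higher. Energy genes had 0.19 (percentile 80.3), with 6 of 6 bins higher, among them the bin of nuoH, nuoI, nuoJ and nuoK at 0.35. Motility genes had -0.02 (percentile 50.4), with 6 of 19 bins higher. Chaperones and stress genes had 0.06 (percentile 93.4), with 4 of 8 bins higher, where dnaJ had 0.38, dnaK 0.36 and grpE 0.31.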

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

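The tests of explanations here were all chosen after the results were seen, and the break, vanillate and library preparation differ together between the libraries.

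The pair of the first and last bin was the only neighbouring pair with a value in the maps, and was not itself compared. It held 0.1167 of a bin's contacts in the break library and 0.0612 in the control, 1.91 times as much in the break library. It counts towards the row sums of these bins, so less is left for their other partners, more so in the break library. With further balancing, which leaves this pair out, the far ratio at oriC was -0.25.

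The contact of the origin region with the terminus in the control library was examined first. A uniform ligation background gives a bin no more contact over 1600 kb away than at 810 to 1200 kb, whereas the ratio at the parAB bin was 2.00 in the control (bootstrap interval over pairs 1.87 to 2.13) and 0.665 in the break library. Ratios above 1 also occur elsewhere, in 44.5% of control bins and 33.3% of break bins more than 100 kb from parAB, so such a ratio is not special to the origin. The ratio is made from the values that had prompted the question, so it is no independent test. It shows only that a uniform background alone does not give the control values at this bin. A sequence of the parAB bin present elsewhere would leave bins 20 to 100 kb away without an excess, whereas 11 of these 18 bins had more than 1.5 times as much contact with the terminus in the control. Origins near the terminus in part of the control cells stay open: the largest excess lay 0 kb from the parAB bin, but that position had prompted the idea and decides nothing. Whether the break, vanillate or a difference in arrest between the cultures set the libraries apart was not tested.

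The higher contact of terminus pairs in the break library was examined in 3 sets of pairs, with other pairs of the same control level as the comparison and contact per 10000. A uniform background raises all pairs of a level alike. Pairs mirrored about oriC in the terminus part gained 8.10 more than other pairs without terminus bins (bootstrap interval over bins 6.83 to 9.07). This is more than such a background gives. These pairs lie beside the inter-arm stripe, however. On the displaced axis of this part the median log2 ratio was -0.27, with 90.8% of pairs lower in the break library. That ratio was not matched on control level, so it is not the same measure as the gain. Whether stripe pairs gained more or less than other pairs of their level was not tested. Pairs between the terminus part and the middle of the arms gained slightly less than the others (-0.50, interval -0.99 to -0.06). Here 13930 of 17804 pairs could be matched. Equal gains would give a difference of 0, so the values show no extra gain of these pairs. They do not show that a uniform background is the source of the rise. Pairs of the interval from 1440 to 2150 kb with the arms, an interval picked from the map, gained 1.59 more (0.883 to 2.10). The comparison here was pairs with both bins outside the interval. Bins within 50 kb of oriC, whose contact with the terminus was lower in the break library, were left out of both sets. Bins were resampled singly although neighbouring bins are correlated, so these intervals may be too narrow. They also do not cover differences between cultures or library preparations. The mirrored pairs were added, and the matching refined, after the pairs with the middle of the arms had given the same outcome as here. A biological cause stays open and untested.

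The decrease of contacts across the van locus was examined last. A faulty bin would not lower contacts between the flanks, yet their median log2 ratio was -0.69 with the van bin and 3 bins to each side left out. A change of contrast of the whole map would keep the van bin near a line of break on control insulation. Fitted to bins more than 200 kb away, the line had a slope of 0.79, and the van bin lay at -0.43 from it, below the lowest of those bins (-0.20, SD 0.096). Transcription induced there by vanillate was not tested, since expression was not measured in the files used here. The strain's insertion at the locus is in both libraries per the labels.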

How the results depend on the processing

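Of the values of 26 results under 21 alternatives, 90.1% moved by less than their spread, or by up to 1.5 times for counts. The sign was opposite in 12, in 3 of them within the spread. Of the alternatives, 4 were chosen after seeing the data: a removed floor, leaving out the last bin, leaving out repeated profiles, and the displaced inter-arm axis. The insulation change at the van locus stayed between -0.52 and -0.40, the far ratio at oriC between -0.41 and -0.14, and the map correlation between 0.84 and 0.88. On the displaced axis the inter-arm ratios turned to -0.30 near oriC (from 0.00), -0.19 in the middle and -0.27 near the terminus. Other pairs are measured there, and near the terminus some of them lie on the same arm. Within 500 kb, 2 of the 10 highest profile changes lay near oriC. The local ratio left of oriC was 0.20 with the split at 400 kb. Insulation over 200 kb gave 0.12 at the right site and 0.27 for energy genes, and turned the left site to -0.17 and the medians of DNA repair genes to 0.055, cell cycle genes to -0.032, replication genes to -0.0069 and chaperones to -0.028. Insulation over 50 kb gave 31 boundaries in the break library, 28 in the control and 24 shared, and 0.059 for cell cycle, 0.068 for ribosomal protein and 0.10 for energy genes, and turned motility genes to 0.026. Without the lowest-total bins, cell cycle genes had 0.036 and energy genes 0.26. Apart from the axis, the cause was not tested. All rows sum to about 1, so the lowest-total bins are set mainly by rounding, apart from the first and last bin. The pair of these bins does not count towards the totals used, so both, including the oriC bin, were left out for that reason. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. The unknown depth and the rounding step of 0.0001 limit weak contacts: 5.03% of control pairs are listed at 0.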

Other observations

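Contacts beyond 200 kb differed by arm and region. Scaling left the break value slightly higher where both maps listed the same value. Shares of pairs higher in the break library therefore include such pairs. Medians leave out pairs listed at 0 in either map, whereas shares and means include them. Between the middle and the terminus-proximal part of the same arm, the median log2 ratio was 0.59. Of all 8692 pairs there, 18 were at 0 in the break library and 490 in the control. Of the 8692, 85.4% were higher in the break library or listed equally. Between those parts of opposite arms the median log2 ratio was 0.21, with 42 of 9112 pairs at 0 in the break library and 1300 in the control. With the uniform floor removed, the median over both kinds of pair fell from 0.42 to 0.12, and the ratio of their means from 1.12 to 0.996. The floor was 2.0 in the break map and 0.0 in the control, so only break values were reduced. A fall of weak contacts follows from this subtraction, so it does not show what had raised them. Between terminus-proximal parts of opposite arms the median log2 ratio, with no floor removed, was 0.68 (4414 pairs). The means there were 28.6 in the break library and 23.2 in the control per 10000. Between the oriC-proximal and terminus-proximal parts the median log2 ratio was 0.00 on the same arm and on opposite arms, the value of equally listed pairs. Of 9180 pairs each, 67.5% and 63.8% were higher in the break library or listed equally. Mean contact on the same arm was 4.17 in the break library and 4.18 in the control. On opposite arms it was lower in the break library, 4.49 against 4.93. A difference as large as that of the oriC window was not seen over the whole oriC-proximal part. Within the oriC-proximal part of 1 arm the median log2 ratio was 0.30, with 84.9% of 2209 pairs higher or listed equally. Within the terminus-proximal part of 1 arm it was 0.00, the value of equally listed pairs, with 50.4% of 2256 pairs higher or listed equally.

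A boundary called in the control only lay at 2560 kb, between the genes pleA and rtrB and the uptake genes exbB, tonB1 and exbD. Contact across it was -0.27 with a depth of 0.43 in the control, and -0.18 with a depth of 0.17 in the break library, where it was no minimum. A dip near 360 to 380 kb was called at 360 kb in the control, beside sucA, sucB and sucD of the citric acid cycle, and at 380 kb in the break library. It was deep in both maps at both positions, with depths of 0.65 to 0.93, so only the called position differed. These genes were named after their values were seen.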
